A study of Mus musculus with 11 samples.

How the data were processed

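Gene expression was measured by RNA sequencing in mouse gastrocnemius muscle, a mixed-fibre calf muscle, collected after 36 h of fasting. Fasting is a standard way of inducing muscle wasting. Per the labels, 4 groups were sequenced: mice with floxed alleles of ZEB1 or of ZEB2 that also carried HSA-Cre, a recombinase driven by the skeletal actin promoter and active in myofibres, and floxed controls of each line. No group carried HSA-Cre without floxed alleles, so neither knockout contrast can tell loss of the ZEB gene from presence of Cre. ZEB1 and ZEB2 are zinc-finger transcription factors, best known as repressors of epithelial genes. Each library held RNA pooled from 2 mice, per the series design text, so p-values measure the spread between pools. The ZEB1 control group had 2 libraries, numbered 2 and 3 in the labels, and each of the other 3 groups had 3 libraries, numbered 1 to 3.

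Libraries were made from total RNA with a stranded, poly(A)-selecting kit, per the labels' protocols. The deposited table holds estimated counts per gene, written by the authors as whole numbers and not normalized. STAR, RSEM and DESeq2 and the build GRCm38 are named in the submitters' processing notes, with no versions. Their settings, the annotation release and the strand setting of the counting are not given in the sources used here. The unit was judged from the values and from the naming of RSEM, which shares reads among similar genes by estimation, so counts of near-identical copies and of overlapping or antisense genes are uncertain. A gene-level count also includes exons outside the deleted part of a floxed gene.

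The table held 55385 genes, of which 54487 had an identifier matching GENCODE M21 (GRCm38) with its version and 55144 matched without it. Coordinates were taken from GENCODE M21, and symbols and gene types from the deposited table. Total counts ran from 27.3 M in ZEB1_control 2 to 46.3 M in ZEB2_KO 2, and 26986 genes had at least 1 count. Replicate pairs differed by far more than counting noise (chi-square per degree of freedom from 15.0 to 100.0), so no library was counted as a duplicate.

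Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 15416 genes holding 99.96% of the counts. Library sizes were scaled by TMM, and all levels are given as TMM-scaled CPM, each count as a share of its scaled library total, computed here. A robust quasi-likelihood fit over the 11 libraries with 4 group means gave each contrast, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 0.240. The contrasts were each knockout against the control of its line, the difference between both knockout effects, and ZEB2 control against ZEB1 control.

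Before the data were examined, 41 gene lists were fixed. They covered protein breakdown (atrophy ubiquitin genes, autophagy and lysosome, proteasome), redox defence (antioxidant enzymes, NRF2 and glutathione) and energy metabolism (nuclear OXPHOS genes, mitochondrial genome, mitochondrial biogenesis, fatty acid and PPAR genes, glycolysis and glycogen). Muscle lists were slow fibre, fast fibre, sarcomere and dystrophin, denervation and neuromuscular junction, and myogenic and satellite cell genes. Stress and signalling lists were ER stress, heat shock, p53, circadian clock, glucocorticoid response, immediate-early genes, hypoxia, interferon, inflammation, TGF-beta and BMP targets, Wnt targets, polyamine and amino acid metabolism, cytosolic ribosome, cell cycle and epithelial genes that ZEB factors repress. Extracellular matrix genes and markers of fibroblasts, tendon, endothelium, smooth muscle and pericytes, macrophages, neutrophils, lymphocytes, erythroid cells, adipocytes and Schwann cells completed the set. Lists with at least 5 tested members were tested by camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. The lymphocyte list had too few tested members, which left 40 lists. Camera with an estimated correlation and fry stood beside it, as did member counts adjusted over the list alone.

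Named genes followed a rule fixed beforehand. They were Zeb1 and Zeb2, the 10 called genes per direction with the largest change, filled up in order of unadjusted p where fewer were called, and up to 3 members of each called list and of the atrophy, antioxidant and NRF2 lists. The top genes had a mean of at least 1 CPM and every knockout library beyond every control library, and unnamed gene models were passed over. The contrast between control groups and the difference of effects named up to 5 called genes per direction. A few genes that this rule selects are not reported here.

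Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, only the groups compared in the fit, replicate numbers as a block, 1 surrogate variable (sva 3.50.0), removal of mitochondrial genes, and omission of each library in turn. Added after the data were seen were the number of males per pool as a covariate, only libraries with Y-linked counts, protein-coding genes only, and omission of ZEB2_KO 3 and ZEB2_control 3 together. The number of males of the 2 pooled mice is not in the labels and was read from Y-linked genes and Xist.

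The procedure was tested on simulated counts drawn from the real means and library sizes. At a fold of 2 it recovered 36.3% of changed genes in the ZEB1 comparison (15198 genes) and 53.3% in the ZEB2 comparison (15174 genes). At a fold of 4 it recovered 88.7% and 89.7%, with 4.34% and 6.33% false calls over both folds. With no change, 0 genes were called in either comparison. Of 10 lists raised 1.4-fold, camera called 9 in the ZEB1 and 10 in the ZEB2 comparison. Genes were drawn independently in these simulations, so they did not test camera where members of a list vary together between libraries.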

Results

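The series asked how loss of ZEB1 or of ZEB2 in myofibres affects gene expression in muscle undergoing fasting atrophy. It comprised 11 libraries, 2 from ZEB1 floxed controls, 3 from ZEB1 knockouts, 3 from ZEB2 floxed controls and 3 from ZEB2 knockouts, each pooled from 2 mice after 36 h of fasting. Total counts averaged 27.8 ± 0.657 M (SD, n = 2) in ZEB1 control, 31.4 ± 1.84 M (n = 3) in ZEB1 knockout, 33.1 ± 2.54 M (n = 3) in ZEB2 control and 40.4 ± 5.32 M (n = 3) in ZEB2 knockout. The mitochondrial genome took 12.1% to 18.0% of counts, with 16.0%, 17.0% and 18.0% in ZEB2 controls and 14.9%, 14.7% and 12.1% in ZEB2 knockouts, and the 10 most abundant genes took 28.1% ± 0.837 and 25.5% ± 1.70 in these groups (SD, n = 3 each). From Y-linked genes and Xist, 4 pools held no male, 3 held 1 male and 4 held 2 males. In order of replicate number, males numbered 0 and 1 in ZEB1 controls, 0, 0 and 2 in ZEB1 knockouts, 1, 2 and 0 in ZEB2 controls and 1, 2 and 2 in ZEB2 knockouts. The first principal component took 42.8% of the variance and the second 14.3%. On the first, the 3 ZEB2 knockout libraries lay at one end (32.1, 32.3 and 81.5), ZEB1_control 2, ZEB2_control 3 and ZEB1_KO 2 at the other (-58.2, -48.7 and -44.9).

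The targeted genes were lower in the knockouts of their own line. Zeb1 (ENSMUSG00000024238.15, GRCm38 chromosome 18, 5591860 to 5775467, plus strand) stood at 41.2 and 51.1 CPM in the 2 ZEB1 controls and at 28.4, 28.6 and 30.4 CPM in the 3 ZEB1 knockouts. Its log2 fold change was -0.67 with an SE of 0.15, and the gene did not pass the test over all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.800). Zeb2 (ENSMUSG00000026872.18, chromosome 2, 44983632 to 45117395, minus strand) stood at 24.1, 23.1 and 25.8 CPM in ZEB2 controls and at 18.3, 14.4 and 17.7 CPM in ZEB2 knockouts. Its log2 fold change was -0.53 with an SE of 0.13 (edgeR, adjusted p = 0.0775). Every library lay on the side its label gives, and where the remaining counts come from was not tested, since whole muscle also holds cells in which HSA-Cre is not active and a gene-level count includes exons outside the deleted part. Zeb2 in the ZEB1 line was 20.8 and 18.7 CPM in controls and 21.8, 19.7 and 20.7 CPM in knockouts. Zeb1 in the ZEB2 line was 47.7, 52.1 and 43.7 CPM in controls and 67.2, 60.2 and 76.0 CPM in knockouts, a log2 fold change of 0.50 with an SE of 0.14 (edgeR, adjusted p = 0.0787).

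**Figure D1:**
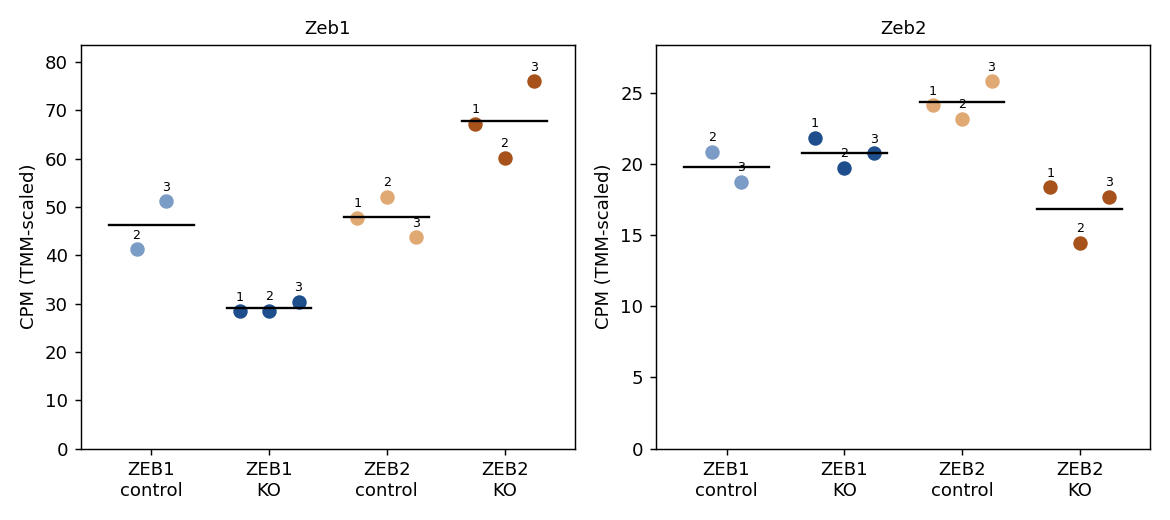
TMM-scaled CPM (y axis) of Zeb1 and Zeb2 in each of the 11 libraries by group (x axis), with replicate numbers at the points and bars at group means. Zeb1 averaged 46.2 CPM in ZEB1 control against 29.1 in ZEB1 knockout, and Zeb2 24.3 CPM in ZEB2 control against 16.8 in ZEB2 knockout.

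In ZEB1 knockouts most of the transcriptome stayed within the spread of replicates, and 0 of 15416 genes passed the edgeR test. Some low-abundance genes were higher in every knockout library than in either control. The single genes named here were chosen partly by such separation, so the separation itself is no support for an effect of the knockout. Cdc42bpg, a kinase that acts downstream of the GTPase Cdc42, averaged 6.09 ± 0.356 CPM (SD, n = 2) in controls and 15.3 ± 1.55 CPM (n = 3) in knockouts. Spint2, a membrane inhibitor of serine proteases, averaged 1.79 ± 0.497 CPM (n = 2) and 5.82 ± 1.68 CPM (n = 3). Noct, a circadian nuclease known as nocturnin, averaged 6.72 ± 0.304 CPM (n = 2) and 13.4 ± 0.798 CPM (n = 3), and Snai3, a member of the Snail repressor family, 7.92 ± 2.05 CPM (n = 2) and 31.7 ± 19.5 CPM (n = 3). Lower in all 3 knockout libraries were Mss51, a muscle protein linked to mitochondrial metabolism (39.8 ± 11.9 CPM, n = 2, against 9.33 ± 6.03, n = 3), and Thbs4, a matrix protein of tendon and muscle (50.9 ± 6.26 CPM, n = 2, against 26.8 ± 4.51, n = 3).

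In the edgeR quasi-likelihood test 0 of 15416 genes passed an adjusted p of 0.05, and 499 had an unadjusted p under 0.05 (253 higher, 246 lower), where chance gives 770.8. DESeq2 called 21 genes (17 rose, 4 fell), limma-voom 1 and edgeR without a low-count filter 6. The largest statistic belonged to Cdc42bpg (chromosome 19, 6306456 to 6325652), with a log2 fold change of 1.33, an SE of 0.17 and adjusted p of 0.105 in edgeR and 8.93e-08 in DESeq2. Spint2 (chromosome 7, 29256323 to 29281912) gave 1.70 with an SE of 0.30 (adjusted p = 0.351 in edgeR, 0.000531 in DESeq2) and Noct 1.00 with an SE of 0.18 (0.366 and 0.00205). Other named genes that DESeq2 called and edgeR did not included Snai3 (log2 fold change 2.00 in edgeR), Hook2 (1.59), Elmo3 (1.47), Catsper4 (1.78), Hpn (0.90), Cdkl2 (0.87), Vamp8 (0.70) and Mss51 (-2.09). Of the 21 DESeq2 calls 6 were unnamed gene models or pseudogenes, among them 3 of the 4 that fell. Fmod (-1.16), BC028528 (-1.06), Xk (-0.83), Nbl1 (-0.69), Itgbl1 (-0.66), Aldh1a1 (-0.60) and Ccdc80 (-0.53) were lower in all knockout libraries and passed neither edgeR nor DESeq2. Every knockout library lay beyond every control library for 13.9% of genes, where chance gives 20%. Leaving out ZEB1_control 2 gave 2 edgeR calls, Rps3a2 and Rps3a3 (named after values were seen), which rest on the 1 remaining control, with 2.27 and 1.12 CPM against 58.3 and 54.1 in ZEB1_control 2. Leaving out ZEB1_KO 2 gave 5, of which 4 were unnamed gene models and 1 was Snai3.

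Epithelial genes that ZEB factors are known to repress were higher as a list in ZEB1 knockouts. Of 14 tested members 8 were higher and 6 lower, with a median log2 fold change of 0.47 and a mean of 0.65. Other members of the fixed list, among them Epcam and Dsp, were not tested. Adjusted over the list alone 5 rose and 0 fell, against 0 over all genes tested. These were Spint2, Crb3 (a cell polarity protein, 3.66 with an SE of 0.81), Marveld2 (tricellulin of tight junctions, 2.13 with an SE of 0.55), Krt18 (a simple-epithelial keratin, 2.15 with an SE of 0.72) and Llgl2 (a polarity protein, 0.60 with an SE of 0.20). Levels were low, with Crb3 at 0.0832 CPM in controls and 1.11 CPM in knockouts. Crb3 reached at most 0.323 CPM in any library outside the ZEB1 knockouts, so it passed the low-count filter through them. Cdh1, which encodes E-cadherin, was at 0.690 and 0.665 CPM in the controls and 0.942, 0.644 and 0.232 CPM in the knockouts. Camera called the list (adjusted p = 0.000388), with adjusted p = 0.154 with an estimated correlation and 0.287 by fry. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 9.83e-06. That mixed test called 1 of 40 lists in the ZEB1 comparison, 26 in the ZEB2 comparison, 4 for the difference and 1 between controls. Without ZEB1_control 2 the median was 0.14 and the call was lost (adjusted p = 0.180), and over omissions the median ran from 0.14 to 1.21. Between ZEB1_KO 1 and ZEB1_KO 2 the list differed by a median of 0.36. In the ZEB2 line the same list had 7 members higher and 7 lower (camera, adjusted p = 0.694).

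**Figure D2:**
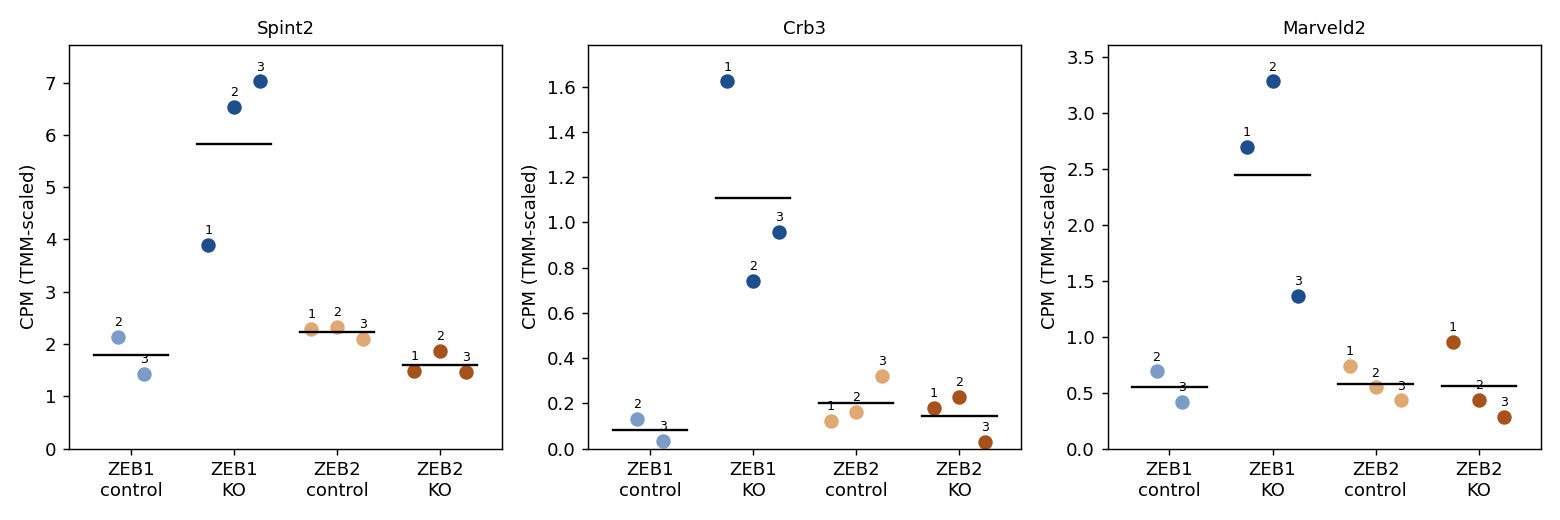
TMM-scaled CPM (y axis) of Spint2, Crb3 and Marveld2, the list members with the lowest p in the ZEB1 comparison, in each library by group (x axis), with replicate numbers at the points and bars at group means. All 3 ZEB1 knockout libraries lie above both ZEB1 controls for each gene, and Spint2 averages 5.82 CPM there against 1.79 in the controls.

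Connective tissue genes were lower as a list in ZEB1 knockouts. Of 32 extracellular matrix genes 31 were lower, with a median log2 fold change of -0.45 (camera, adjusted p = 3.38e-11, and adjusted p = 0.645 with an estimated correlation). Thbs4 fell when adjusted over the list alone (-0.93 with an SE of 0.20), and the laminin subunits Lamb1 (-0.44) and Lama2 (-0.37) did not pass. All 9 tendon markers were lower, median -0.97 (camera, adjusted p = 9.48e-05, and adjusted p = 0.645 with an estimated correlation), and 1 of them, Fmod, fell when adjusted over the list alone, with Cilp2 at -1.77 and Kera at -1.82. Fibroblast markers were lower for 16 of 18 genes, median -0.40 (camera, adjusted p = 9.01e-05, and adjusted p = 0.645 with an estimated correlation), among them Dcn (-0.41), Gsn (-0.39) and Serping1 (-0.31). Interferon response genes were lower for 24 of 26, median -0.42 (camera, adjusted p = 3.50e-07, and adjusted p = 0.645 with an estimated correlation), with Ifit1 at -1.03, Ifit2 at -0.63 and Oas1a at -1.46. In neither of the last 2 lists did a member pass when adjusted over the list alone. The matrix list was called in each omission of 1 library, whereas omission of ZEB1_control 2 ended the calls of the tendon (adjusted p = 0.145), fibroblast (0.124) and interferon (0.991) lists, with medians of -0.54, -0.13 and 0.010. In other omissions the interferon median reached -0.81. Libraries of the same group also differed in matrix genes. The matrix median was -0.49 for ZEB1_KO 1 minus ZEB1_KO 2 and -0.31 for ZEB1_control 3 minus ZEB1_control 2.

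Markers of macrophages, Schwann cells and red cells were also lower in ZEB1 knockouts, with no member passing when adjusted over its list alone. Macrophage markers were lower for 16 of 20 genes, median -0.25 (camera, adjusted p = 0.00969, and adjusted p = 0.801 with an estimated correlation), with Csf1r at -0.36, Ptprc at -0.47 and C1qb at -0.31. Schwann cell markers were lower for 12 of 12, median -0.23 (camera, adjusted p = 0.0197, and adjusted p = 0.870 with an estimated correlation), with Mbp at -0.57, Prx at -0.52 and S100b at -0.54. Erythroid markers were lower for 7 of 8, median -0.25 (camera, adjusted p = 0.0480, and adjusted p = 0.772 with an estimated correlation), with Hba-a1 at -0.33 and Hba-a2 at -0.35. The macrophage call was lost without ZEB1_control 2 (adjusted p = 0.478) or ZEB1_KO 3 (0.641), and the Schwann call without ZEB1_control 3 (0.686) or ZEB1_KO 3 (0.689). The erythroid call was lost without ZEB1_control 2 (0.212), ZEB1_control 3 (0.160), ZEB1_KO 1 (0.107) or ZEB1_KO 2 (0.436). Over omissions the medians ran from -0.41 to -0.062 for macrophage, -0.60 to 0.092 for Schwann cell and -0.42 to -0.14 for erythroid markers.

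Nuclear genes of oxidative metabolism were slightly higher in ZEB1 knockouts, and slow-fibre genes were lower. Genes of the mitochondrial genome were not called, with 5 higher, 8 lower and a median of -0.042 (camera, adjusted p = 0.916). Nuclear OXPHOS genes were higher for 58 of 59, median 0.11 (camera, adjusted p = 0.000161, and adjusted p = 0.870 with an estimated correlation), with Atp5d at 0.29, Cox5a at 0.26 and Atp5b at 0.21. Fatty acid and PPAR genes were higher for 30 of 34, median 0.24 (camera, adjusted p = 0.000366, and adjusted p = 0.801 with an estimated correlation), with Cpt1b, the muscle carnitine palmitoyltransferase, at 0.51, Ppara at 0.97 and Slc25a20 at 0.41. Mitochondrial biogenesis genes were higher for 18 of 20, median 0.17 (camera, adjusted p = 0.00691, and adjusted p = 0.645 with an estimated correlation), with Ppargc1a, a coactivator of that programme, at 2.44 with an SE of 0.98, Perm1 at 0.67 and Polrmt at 0.24. Ppargc1a stood at 344.8 CPM in ZEB1_KO 1 and at 24.5 and 35.3 CPM in the other knockouts, against 23.5 and 26.2 CPM in controls. Slow-fibre genes were lower for 15 of 17, median -0.35 (camera, adjusted p = 0.0150, and adjusted p = 0.868 with an estimated correlation), with Mb at -0.39 and Casq2 at -0.76, while Ankrd2 was at 0.70. No member of these 4 lists passed when adjusted over its list alone. Calls were lost without ZEB1_control 3 for OXPHOS (adjusted p = 0.0862), fatty acid (0.0701) and biogenesis genes (0.103), without ZEB1_KO 1 for OXPHOS (0.426), biogenesis (0.393) and slow-fibre genes (0.312), and without ZEB1_control 2 for slow-fibre genes (0.888). Over omissions the medians ran from 0.028 to 0.16 for OXPHOS, 0.15 to 0.38 for fatty acid, 0.077 to 0.25 for biogenesis and -0.69 to 0.089 for slow-fibre genes.

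The remaining calls in ZEB1 knockouts were of small size, and no member of these lists passed when adjusted over its list alone. Cytosolic ribosomal genes were higher for 44 of 46, median 0.096 (camera, adjusted p = 0.000394, and adjusted p = 0.870 with an estimated correlation), with Rplp2 at 0.18, Rps13 at 0.17 and Rpl13 at 0.16. Heat shock genes were higher for 16 of 20, median 0.14 (camera, adjusted p = 0.0477, and adjusted p = 0.870 with an estimated correlation), with Hspb8 at 0.54, Hspe1 at 0.34 and Hspa9 at 0.26. TGF-beta and BMP targets were lower for 13 of 22, median -0.092 (camera, adjusted p = 0.0346, and adjusted p = 0.645 with an estimated correlation), with Id2 at -0.71, Fst at -0.60 and Bambi at -0.58. Wnt targets were lower for 9 of 11, median -0.32 (camera, adjusted p = 0.0372, and adjusted p = 0.645 with an estimated correlation), with Axin2 at -0.93, Wif1 at -1.48 and Tcf7 at -0.47. Omission of ZEB1_control 2 ended all 4 calls (adjusted p = 0.255, 0.785, 0.502 and 0.374 in that order). Over omissions the medians ran from 0.059 to 0.10 for ribosomal, -0.032 to 0.29 for heat shock, -0.24 to -0.018 for TGF-beta and -0.39 to -0.011 for Wnt genes. Without ZEB1_KO 1 the heat shock (0.0991), TGF-beta (0.0588) and Wnt (0.108) calls were lost, without ZEB1_KO 3 the same lists (0.966, 0.155 and 0.196), and without ZEB1_control 3 the Wnt call (0.0667).

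Genes of muscle wasting and redox defence did not pass as lists in ZEB1 knockouts. Atrophy ubiquitin genes had a median of 0.086, with 17 higher and 8 lower (camera, adjusted p = 0.251), with Asb2 at 0.48 and Usp19 at 0.17. Antioxidant enzymes had a median of 0.081 (adjusted p = 0.493), with Txnrd1 at 0.60, Txnrd2 at 0.29 and Sesn3 at -0.55. NRF2 and glutathione genes had a median of 0.013 (adjusted p = 0.764), with Mgst3 at 0.43, Ftl1 at 0.36 and Tkt at -0.58. The atrophy list was called lower without ZEB1_control 2 (median -0.45, adjusted p = 0.0265) and higher without ZEB1_control 3 (0.86, adjusted p = 7.10e-06) or ZEB1_KO 2 (0.27, adjusted p = 0.0212). In all, camera called 16 of 40 lists, 6 higher and 10 lower, while an estimated correlation and fry's directional test called 0, with a smallest adjusted p of 0.154 and 0.287.

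ZEB2 knockouts differed from the controls of their line by a broad shift. This contrast by itself cannot tell loss of ZEB2 from presence of Cre. Protein-breakdown and ribosomal genes were higher. Genes of the matrix, of slow fibres and of several other cell types were lower. Nuclear OXPHOS genes, genes of the mitochondrial genome and fatty acid genes were not called by camera. Nuclear OXPHOS genes averaged 7.99 ± 0.0798 log2 CPM (SD, n = 3) in controls and 7.94 ± 0.195 (n = 3) in knockouts. Myh2, the myosin of fast oxidative fibres, averaged 2812 ± 620 CPM (SD, n = 3) in controls and 964 ± 290 CPM (n = 3) in knockouts. Nes, the intermediate filament nestin, averaged 34.7 ± 6.66 CPM (n = 3) and 15.6 ± 2.41 CPM (n = 3). Foxo1, a transcription factor that drives atrophy genes, averaged 53.5 ± 21.3 CPM (n = 3) and 188.4 ± 61.1 CPM (n = 3). Sqstm1, the autophagy receptor p62, averaged 857.9 ± 267 CPM (n = 3) and 2001 ± 374 CPM (n = 3). Both also varied widely without Cre. In ZEB1_control 2 and ZEB1_control 3, Foxo1 stood at 31.6 and 130.9 CPM and Sqstm1 at 521.1 and 1174 CPM. Rps14, of the small ribosomal subunit, averaged 265.7 ± 13.9 CPM (n = 3) and 390.5 ± 16.7 CPM (n = 3).

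The edgeR quasi-likelihood test called 0 genes at an adjusted p of 0.05, the smallest being 0.0775. At an unadjusted p under 0.05 there were 5113 genes (2453 higher, 2660 lower) where chance gives 770.8, and at an adjusted p under 0.1 there were 2649 (1224 higher, 1425 lower). DESeq2 called 2519 genes (1360 rose, 1159 fell), edgeR fitted on the ZEB2 line alone 2077 (1117 rose, 960 fell), edgeR without a low-count filter 348 and limma-voom 0. Every knockout library lay beyond every control library for 43.4% of genes, where chance gives 10%. Without ZEB2_control 3 the genes at an unadjusted p under 0.05 numbered 2488, without ZEB2_KO 3 2708 and without both 1135. With 1 surrogate variable they numbered 757, below the chance number, and the smallest adjusted p was 0.954. That variable followed the first principal component over the libraries (Pearson 0.999). Among the named genes with the lowest p, all at an edgeR adjusted p of 0.0775, the lower ones were Nes (-1.15 with an SE of 0.18), Myh2 (-1.54 with an SE of 0.24), Kcna7 (-1.36), Myom3 (-1.15), Lhfpl2 (-1.57), Dach2 (-1.53), Plk2 (-0.80), Sh3kbp1 (-1.55) and Cenpc1 (-1.42). The higher ones were Rnf126, a ubiquitin ligase (0.83), Eif4ebp3 (1.69), Fau (0.60), Mcrip1 (0.81), Fth1, the ferritin heavy chain (0.61), Rps14 (0.56), Aup1 (0.70), Exosc5 (0.74) and Znhit2 (0.81).

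Genes of protein breakdown were higher in ZEB2 knockouts. All 31 proteasome genes rose when adjusted over the list alone, with a median of 0.76 (camera, adjusted p = 1.53e-12, and adjusted p = 0.492 with an estimated correlation), among them Psmb1 (0.89), Psmb4 (0.90) and Psmc3 (0.69). Autophagy and lysosome genes were higher for 27 of 29, median 0.53, and 10 rose when adjusted over the list alone (camera, adjusted p = 2.84e-07, and adjusted p = 0.492 with an estimated correlation), with Sqstm1 at 1.22, Gabarap at 0.53 and Gabarapl2 at 0.46. Atrophy ubiquitin genes were higher for 21 of 25, median 1.08, with 0 passing when adjusted over the list alone (camera, adjusted p = 0.000392, and adjusted p = 0.492 with an estimated correlation). Of these, Foxo1 stood at 1.82 with an SE of 0.52, Ubb at 1.31 with an SE of 0.38 and Fbxo40 at -0.58. Fbxo32 and Trim63, the atrophy ubiquitin ligases atrogin-1 and MuRF1, were named here after their values were seen. Fbxo32 stood at 1.20 with an SE of 0.46 and Trim63 at 1.48 with an SE of 0.71, and neither passed (edgeR, adjusted p = 0.113 and 0.175). Glucocorticoid response genes were higher for 19 of 20, median 1.26, and 4 rose when adjusted over the list alone (camera, adjusted p = 5.98e-06, and adjusted p = 0.492 with an estimated correlation), with Gadd45g at 2.74, Errfi1 at 1.72 and Cebpb at 1.24.

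**Figure D3:**
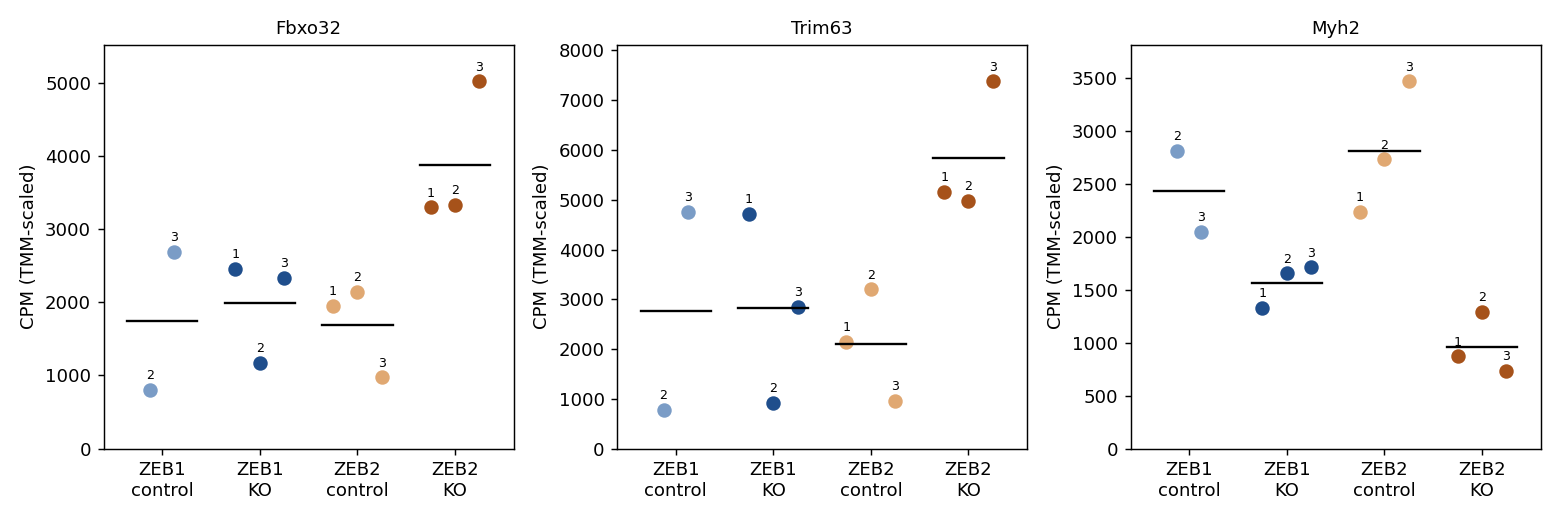
TMM-scaled CPM (y axis) of Fbxo32, Trim63 and Myh2 in each library by group (x axis), with replicate numbers at the points and bars at group means. Fbxo32 lies at 3300, 3330 and 5024 CPM in the ZEB2 knockouts, above all other libraries, while the 2 ZEB1 controls lie at 802 and 2690 CPM.

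Ribosomal genes and several stress lists were also higher in ZEB2 knockouts. All 46 cytosolic ribosomal genes were higher, median 0.42, and 42 rose when adjusted over the list alone (camera, adjusted p = 5.57e-19, and adjusted p = 0.492 with an estimated correlation), including Rps27 (0.67) and Rpl10a (0.55). Genes of polyamine and amino acid metabolism were higher for 19 of 25, median 0.27, with 0 passing when adjusted over the list alone (camera, adjusted p = 0.00861, and adjusted p = 0.492 with an estimated correlation), with Slc3a2 at 0.95, Gpt2 at 0.84 and Bckdha at 0.63. The p53 targets were higher for 15 of 20, median 0.57 (camera, adjusted p = 0.0197, and adjusted p = 0.492 with an estimated correlation), with 4 rising and 1 falling when adjusted over the list alone, Mdm2 at 0.77, Sesn2 at 0.94 and Plk2 at -0.80. ER stress genes were higher for 21 of 29, median 0.19 (camera, adjusted p = 0.0333, and adjusted p = 0.539 with an estimated correlation), with 7 rising and 2 falling when adjusted over the list alone, Ern1, the IRE1 sensor, at 1.32 and Pdia4, a protein disulfide isomerase, at -0.86. The p53 call was lost without ZEB2_control 1 (adjusted p = 0.0912), and the ER stress call without ZEB2_control 1 (0.0824) or ZEB2_KO 3 (0.0751), with the ER stress median from 0.099 to 0.35 over omissions.

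Matrix and tendon genes were lower in ZEB2 knockouts, while fibroblast markers were not called (5 higher, 13 lower, median -0.29, camera adjusted p = 0.140). Of 32 extracellular matrix genes 31 were lower, median -0.86, and 27 fell when adjusted over the list alone (camera, adjusted p = 5.68e-09, and adjusted p = 0.492 with an estimated correlation). Sparc stood at -0.83, Fbn1, which encodes fibrillin-1, at -1.19 and Fn1, which encodes fibronectin, at -1.08. All 9 tendon markers were lower, median -1.66, and 7 fell when adjusted over the list alone (camera, adjusted p = 0.000934, and adjusted p = 0.492 with an estimated correlation), with Fmod at -1.48, Comp at -1.66 and Kera at -2.44. TGF-beta and BMP targets were lower for 20 of 22, median -0.31, and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0171, and adjusted p = 0.492 with an estimated correlation), with Tgfb2 at -1.46, Id2 at -0.64 and Tgif1, a repressor of the pathway, at 1.04.

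Markers of several other cell types were lower in the same libraries, while Schwann cell (median -0.75, camera adjusted p = 0.0606) and erythroid markers (-0.31, 0.183) were not called. Macrophage markers were lower for 19 of 20, median -0.61, and 8 fell when adjusted over the list alone (camera, adjusted p = 0.000225, and adjusted p = 0.492 with an estimated correlation), with F13a1 at -0.78, Mrc1 at -0.90 and Aif1 at -1.45. Interferon genes were lower for 23 of 26, median -0.56, with 0 passing when adjusted over the list alone (camera, adjusted p = 0.000565, and adjusted p = 0.539 with an estimated correlation), with Gbp2 at -1.11 and Ifit2 at -0.60. Smooth muscle and pericyte markers were lower for 12 of 14, median -0.44, with 9 falling and 1 rising when adjusted over the list alone (camera, adjusted p = 0.00698, and adjusted p = 0.492 with an estimated correlation), with Acta2 at -0.70, Cspg4 at -0.97 and Itga1 at -0.69. Adipocyte markers were lower for 13 of 15, median -1.04, and 1 fell when adjusted over the list alone (camera, adjusted p = 0.0117, and adjusted p = 0.539 with an estimated correlation), with Fasn at -2.17, Plin1 at -2.28 and Adrb3 at -2.51. The adipocyte median ran from -1.84 without ZEB2_KO 1 to -0.51 without ZEB2_control 1. Endothelial markers were lower for 15 of 18, median -0.28, and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0482, and adjusted p = 0.580 with an estimated correlation), with Tek at -0.61, Kdr at -0.93 and Ecscr at -0.52. The endothelial call was lost without ZEB2_control 1 (adjusted p = 0.201), ZEB2_KO 2 (0.134) or ZEB2_KO 3 (0.0536).

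Slow-fibre and neuromuscular genes were lower too, while redox lists did not pass in the main fit but were close to the threshold. Slow-fibre genes were lower for 16 of 17, median -0.61, with 0 passing when adjusted over the list alone (camera, adjusted p = 0.00453, and adjusted p = 0.539 with an estimated correlation), with Casq2 at -1.62, Myh7, the slow myosin, at -1.05 and Mb at -0.49. Without ZEB2_KO 3 the slow-fibre median was -0.34. Denervation and neuromuscular junction genes were lower for 17 of 21, median -0.47, with 11 falling and 2 rising when adjusted over the list alone (camera, adjusted p = 0.00861, and adjusted p = 0.492 with an estimated correlation). Among them, Dach2, a corepressor responsive to nerve activity, stood at -1.53, Myh8, the perinatal myosin, at -0.97 and Colq, the collagen tail of acetylcholinesterase, at -0.91. Antioxidant enzymes had a median of 0.19 (camera, adjusted p = 0.0758), with Prdx1 at 0.73, Sesn2 at 0.94 and Gpx8 at -1.09. NRF2 and glutathione genes had a median of 0.23 (adjusted p = 0.0652), with 4 rising and 3 falling when adjusted over the list alone, Fth1 at 0.61, Tkt at -1.06 and G6pdx at -0.76. Both redox lists were called higher without ZEB2_control 2 (adjusted p = 0.0307 and 0.0385 in that order), and the antioxidant list also without ZEB2_KO 3 (0.0370). Camera called the antioxidant list higher too in the fit of the ZEB2 line alone (adjusted p = 0.0348) and with the replicate block by title number (0.0405). The same held without ZEB2_KO 3 and ZEB2_control 3 together (0.0386). Camera called 18 of 40 lists, 8 higher and 10 lower, an estimated correlation 0 (smallest adjusted p 0.492) and fry's directional test 5, namely ribosome (0.00399), denervation (0.0119) and matrix, smooth muscle and TGF-beta genes (0.0280 each). Of the 18 camera calls 15 were kept in each omission of 1 library.

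**Figure D4:**
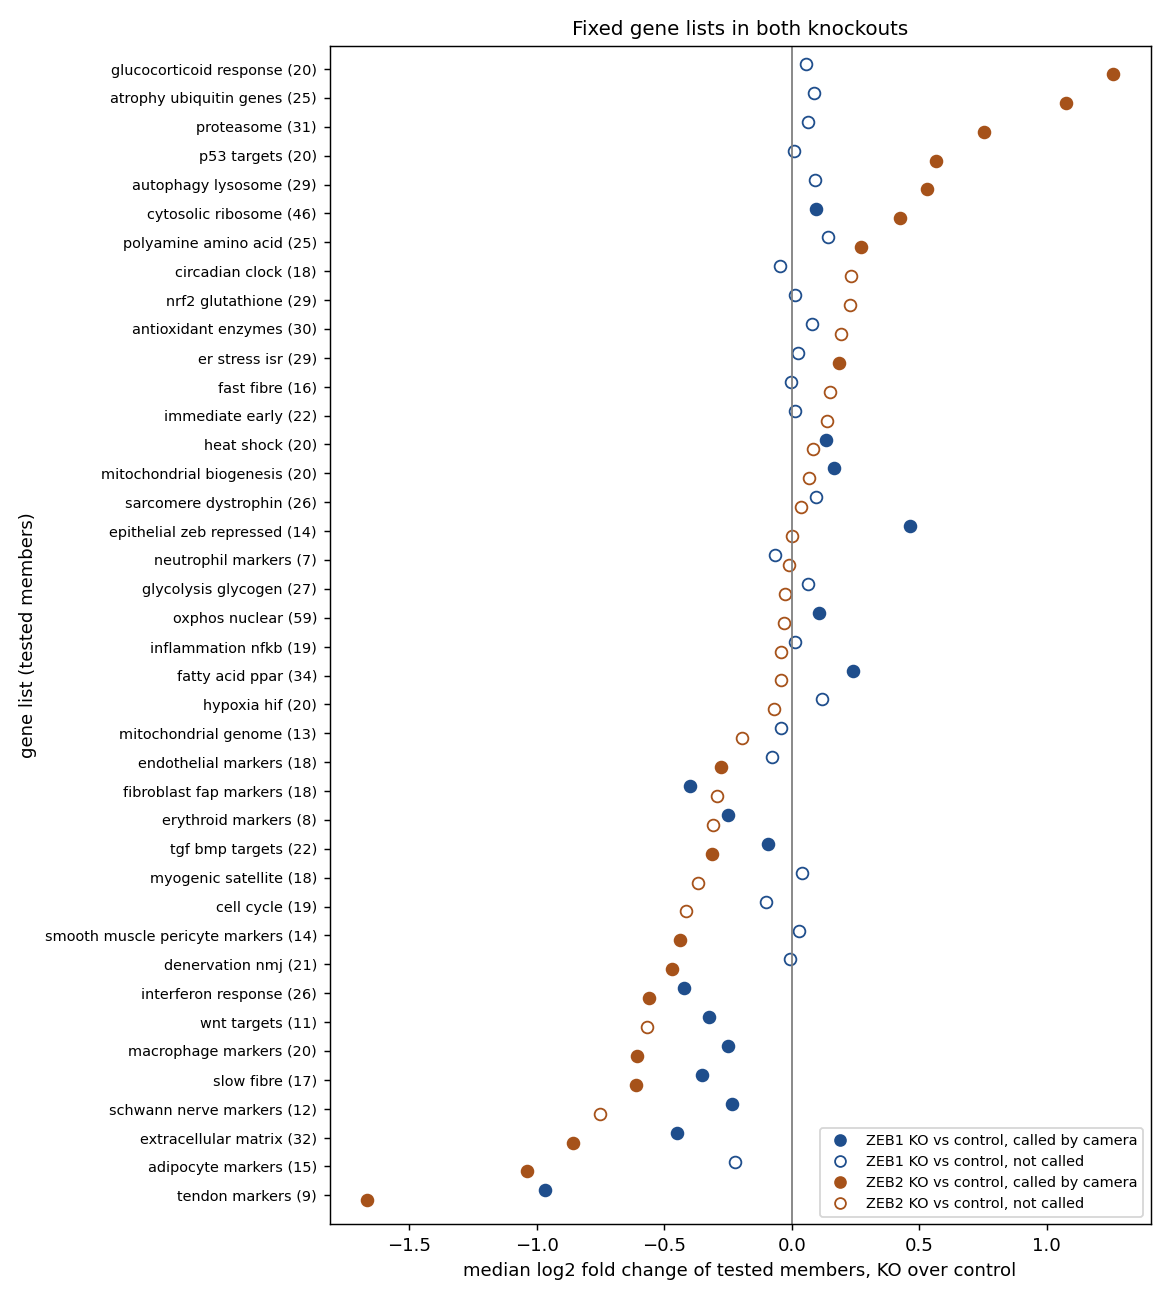
Median log2 fold change of tested members, knockout over control (x axis), for 40 gene lists with their number of tested members (y axis), in the ZEB1 (blue) and ZEB2 (brown) comparisons, with filled points for lists called by camera. Protein-breakdown lists lie far to the right for ZEB2 alone, such as proteasome at 0.76, and tendon and matrix lists lie to the left for both.

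Whether both knockouts act differently was tested as the difference of their effects, ZEB1 minus ZEB2. Proteasome, autophagy, atrophy, glucocorticoid, p53 and ribosomal genes had a less positive fold change in the ZEB1 line, with medians of -0.69 for proteasome genes (31 of 31 negative) and -0.31 for ribosomal genes (46 of 46 negative). Matrix, smooth muscle, macrophage, denervation and OXPHOS genes had a more positive one, such as 0.49 for denervation genes (16 of 21 positive). Camera called these 11 lists, with adjusted p = 1.53e-13 for ribosomal, 1.29e-10 for proteasome, 1.23e-05 for autophagy and 0.00997 for denervation genes, the 4 calls kept in each omission of 1 library. None of the 11 was called with an estimated correlation, where adjusted p ran from 0.735 to 0.818, nor by fry (smallest adjusted p 0.178), and 0 members passed when adjusted over these lists alone. The atrophy call (camera, adjusted p = 0.00796) was lost without ZEB1_control 3 (0.654, with a median of 0.013), ZEB1_KO 2 (0.0575) or ZEB2_KO 3 (0.0560), and the glucocorticoid call (8.49e-05) without ZEB1_control 3 (0.447, with a median of -0.17). Over omissions the medians of the calls that were kept ran from -1.08 to -0.28 for proteasome, -0.59 to -0.20 for autophagy, -0.40 to -0.26 for ribosomal and 0.28 to 0.69 for denervation genes. The smooth muscle call (0.00453) was lost without ZEB1_KO 1 (0.0673), and the matrix, macrophage, OXPHOS and p53 calls were lost in 6, 7, 5 and 5 of the 11 omissions.

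Among single genes edgeR called 0 for this difference, limma-voom 0 and DESeq2 15 (11 positive, 4 negative). In edgeR 1427 genes had an unadjusted p under 0.05 (784 positive, 643 negative), where chance gives 770.8. From the DESeq2 calls, Cdc42bpg (adjusted p = 7.35e-07), Noct (0.000627), Spint2 (0.00351) and Zeb1 itself (0.00338) are named here after their values were seen, as are Kcna7 and Nes (0.0259 each). In edgeR, Cdc42bpg differed by 1.75 with an SE of 0.23 (adjusted p = 0.139), having stood at 6.24 ± 0.598 CPM in ZEB2 controls and 4.65 ± 0.529 CPM in ZEB2 knockouts (SD, n = 3 each). Removing ZEB1_control 2 gave 2 edgeR calls and removing ZEB1_KO 2 gave 3. Across the 15416 genes, which are not independent replicates, the fold changes of both knockouts correlated with a Spearman coefficient of 0.271 and a Pearson coefficient of 0.172, and 61.0% had the same sign. The Spearman value was -0.29 without ZEB1_control 2, 0.65 without ZEB1_control 3, 0.039 without ZEB1_KO 1 and 0.44 without ZEB1_KO 2.

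The control groups of both lines, fasted alike and without Cre, differed in few single genes. Only Gm3375, Gm7887 and Gm5503 passed, all processed pseudogenes, lower in ZEB2 controls and named here after their values were seen. Gm3375 (chromosome 7, 3181093 to 3181888) averaged 13.3 ± 2.99 CPM (SD, n = 2) in ZEB1 controls and 0.220 ± 0.0506 CPM (n = 3) in ZEB2 controls, a log2 difference of -5.90 (edgeR, adjusted p = 5.87e-06). Gm7887 (chromosome 6, 48524554 to 48525090) differed by -4.37 (adjusted p = 0.0161) and Gm5503 (chromosome 18, 33384398 to 33384955) by -5.28 (adjusted p = 0.0276). At an unadjusted p under 0.05 there were 512 genes, and 16.6% of genes had groups that did not overlap, where chance gives 20%. DESeq2 called 16 genes, and omission of ZEB2_control 1 or of ZEB2_control 2 left 1 edgeR call.

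As lists, OXPHOS genes (median 0.13), genes of the mitochondrial genome (0.21), tendon markers (0.80), erythroid markers (0.37) and sarcomere genes (0.20) were higher in ZEB2 than in ZEB1 controls by camera, with adjusted p of 0.000304, 0.00108, 0.00642, 0.0102 and 0.0102. Fibroblast markers (-0.29), macrophage markers (-0.19), glucocorticoid response genes (-0.68) and immediate-early genes (-0.71) were lower, with adjusted p of 0.00108, 0.00694, 0.00694 and 1.54e-05. Every one of the 9 calls was lost with an estimated correlation, with adjusted p = 0.737 with an estimated correlation at the lowest and 0.850 at the highest, and fry called 0 (smallest adjusted p 0.843). No member passed when adjusted over these 9 lists alone. Over omissions the medians ran from 0.059 to 0.15 for OXPHOS, 0.51 to 1.33 for tendon and 0.049 to 0.25 for sarcomere genes. They ran from -0.36 to -0.049 for macrophage markers and from -0.78 to -0.43 for immediate-early genes. Each of the 9 calls was also lost in at least 1 omission, with 5 lost without ZEB1_control 2, 4 without ZEB1_control 3, 3 without ZEB2_control 3, 2 without ZEB2_control 1 and 1 without ZEB2_control 2. Without ZEB1_control 3 the glucocorticoid list was called higher, with a median of 0.43 (camera, adjusted p = 0.0130).

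Several lists were called in no comparison, whatever the size of their medians. Fast-fibre genes had medians of -0.0021 in the ZEB1 and 0.15 in the ZEB2 comparison, glycolysis and glycogen genes 0.065 and -0.025, myogenic and satellite cell genes 0.040 and -0.37, and cell cycle genes -0.10 and -0.41. Circadian clock genes stood at -0.044 and 0.23, hypoxia genes at 0.12 and -0.070, inflammation genes at 0.014 and -0.042, and neutrophil markers at -0.066 and -0.012. Medians and means had opposite signs in the ZEB1 comparison for glucocorticoid, p53 and neutrophil genes, and in the ZEB2 comparison for fast-fibre, sarcomere, epithelial, mitochondrial biogenesis, neutrophil and hypoxia genes. Camera's direction went against the median for p53 genes in the ZEB1 comparison and for epithelial, sarcomere, inflammation, fatty acid and neutrophil genes in the ZEB2 comparison, none of which was called.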

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

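Of the tests in this part, those on the number of males, on the differences between the 2 ZEB1 control libraries and between ZEB1_KO 1 and ZEB1_KO 2, and on called genes and called lists under other splits of the ZEB2 libraries were chosen after the result was seen.

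The fold changes of both knockouts differed by camera for 11 lists, with the median given as ZEB1 minus ZEB2. More negative in the ZEB1 line were glucocorticoid response (-1.12), atrophy ubiquitin (-0.96), proteasome (-0.69), p53 (-0.58), autophagy and lysosome (-0.46) and cytosolic ribosome genes (-0.31). More positive were denervation (0.49), extracellular matrix (0.44), smooth muscle and pericyte (0.44), macrophage (0.42) and nuclear OXPHOS genes (0.16). With an estimated correlation 0 of these lists were called, and 4 of them, the ribosome, proteasome, autophagy and denervation lists, kept their camera call in each omission of 1 library. Sizes depended on single libraries. Without ZEB1_control 3 the atrophy median was 0.013 and the glucocorticoid median -0.17. The smallest difference over omissions was -0.28 for proteasome and -0.20 for autophagy genes. Medians ran from -0.84 to -0.099 for p53, 0.25 to 0.65 for matrix, 0.22 to 0.59 for macrophage and 0 to 0.23 for OXPHOS genes.

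The wide shift in ZEB2 knockouts, with 5113 genes at an unadjusted p under 0.05, was set against 4 other sources and was not kept with 1 surrogate variable, which left 757 genes where chance gives 770.8, with a median absolute log2 fold change of 0.20 (median SE 0.26) against 0.39 (0.23) without it. Thinning to the smallest total (4979 genes) and removal of trends on GC content and exon length (5301 genes) argued against depth and those trends as the whole source, and the number of males as a covariate left 3592, which argued against sex as the whole source. A fasting response that differs in degree between pools whatever their genotype could add to the shift, since the difference of ZEB1_control 3 from ZEB1_control 2, both without Cre, followed the ZEB2 fold changes across genes, which are not independent replicates (Spearman 0.681), and covered atrophy (median 1.48) and proteasome genes (0.81). Against it as the whole source, ribosomal genes differed by only 0.032 between those controls against 0.42 in ZEB2 knockouts, and matrix genes by -0.31 against -0.86, but glucocorticoid (1.94 against 1.26), slow-fibre (-0.76 against -0.61) and adipocyte genes (-0.80 against -1.04) moved about as far between those controls, and ZEB1_KO 1 differed from ZEB1_KO 2 by -0.41 for denervation and -0.49 for matrix genes. The surrogate variable followed the first component (Pearson 0.999) and lay 57.0% between groups. It therefore cannot separate an effect of ZEB2 loss on the fasting response from pools further into it or from technical variation not tested here. All libraries came from fasted mice and none from fed mice, so the fasting response itself was not measured. The part of sex stays open too. The 3 libraries lowest on that component held no male, but neither did ZEB1_KO 1, at 13.2.

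The 6 ZEB2 libraries allow only 10 splits into groups of 3, too few for a p-value under 0.05. For genes at an unadjusted p under 0.05 the real split gave 5113 and the highest other 1122, so 1 of 10 splits reached the real value. For called genes 10 of 10 splits gave 0 in the 4-group fit, and in a fit of the ZEB2 line alone the real split gave 2077 and the highest other 2. For called lists the real split gave 18 and the highest other 19, with 3 of 10 reaching the real value.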

How the results depend on the processing

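Of the alternatives in this part 4 (number of males, only libraries with Y-linked counts, protein-coding genes only, and omission of ZEB2_KO 3 and ZEB2_control 3 together) were chosen after the result was seen. For ZEB1 knockouts 0 genes were called by edgeR, 21 by DESeq2, 6 without a low-count filter, 2 with 1 surrogate variable, 1 by limma-voom, 9 with only Y-count libraries and 0 to 5 when 1 library was omitted. Y-count libraries left 1 library in each ZEB1 group, and omission of a ZEB1 control left 1 control, so the spread there came from the other groups. The Y-count setting, 1 male against 2 in the ZEB1 line, did not hold sex constant. For ZEB2 knockouts 0 were called, against 2519 by DESeq2, 2077 with only these groups in the fit, 348 without a low-count filter, 2649 at an adjusted p under 0.1, and 0 in each omission. With 1 surrogate variable 0 were called too, and the genes at an unadjusted p under 0.05 went from 5113 to 757, with a smallest adjusted p of 0.954 against 0.0775. For the difference of effects 0 were called, against 15 by DESeq2, 2 without a low-count filter, 9 with only Y-count libraries and 0 to 3 over omissions. Between controls 3 were called, against 16 by DESeq2, 7 without a low-count filter, 6 at an adjusted p under 0.1, 5 with RLE factors, 8 with only Y-count libraries, 0 among protein-coding genes, 1 with a replicate block by either numbering and 1 to 4 over omissions.

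Camera called 16 lists for ZEB1, 18 for ZEB2, 11 for the difference and 9 between controls. With an estimated correlation it called 0 in all 4, and fry called 0, 5, 0 and 0. Omission of 1 library gave 8 to 22, 17 to 21, 6 to 14 and 9 to 14. The number of males as a covariate left 7 for the difference, only Y-count libraries gave 14 between controls, and the replicate block by title number gave 9, 20, 10 and 11. Deviations from group means did not pair by title number (pairing r from -0.31 to 0.46), so the block was kept as an alternative only. Omission of ZEB2_KO 3 and ZEB2_control 3 together left 20 ZEB2 lists and 1135 genes at an unadjusted p under 0.05. The correlation of effects ran from -0.29 to 0.65 over omissions.

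Directions turned in the ZEB1 comparison with only Y-count libraries for Hba-a2 (0.016), Usp19 (-0.078), the atrophy (-0.40), erythroid (0.016) and slow-fibre (0.050) lists, and the median of the epithelial list was -0.13 there. The atrophy list was at -0.081 with the replicate block. Over omissions the ZEB1 medians ran from -0.45 to 0.86 for atrophy, -0.69 to 0.089 for slow-fibre, -0.60 to 0.092 for Schwann cell and -0.053 to 0.11 for NRF2 genes, and Zeb2 from -0.015 to 0.13. Without ZEB1_control 2 the interferon median was 0.010, heat shock -0.032 and fibroblast -0.13. The macrophage list in the difference was at -0.046 with only Y-count libraries, Slc3a2 in ZEB2 knockouts at -0.0052 with 1 surrogate variable, and the glucocorticoid list between controls ran from -1.31 to 0.43. For all these the cause was not tested.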

Other observations

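In this part, the tests on the Rps3a sum, on 31-base words and on noise near the detection floor were chosen after the result was seen, as were the single-library genes named below.

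Some genes stood out in 1 library by more than 4-fold beyond the other 10, out of 12378 genes compared. ZEB1_KO 1 was high in Ppargc1a (344.8 CPM, next 47.8), Cish, a target of cytokine and growth hormone signalling (128.2, next 22.4), and Armc2 (5.16, next 1.15). ZEB1_control 3 was low in the HSP70 family genes Hspa1l (0.280, next 8.50) and Hspa1a (0.140, next 2.32). ZEB2_KO 3, the library furthest along the first component, was low in 16 genes, among them the muscle water channel Aqp4 (0.450, next 3.86), the muscle kinase Mylk4 (20.7, next 86.8) and Ky (2.14, next 13.2), a protein needed for muscle maintenance. Atrophy genes varied within groups. Trim63 stood at 770 and 4750 CPM in the 2 ZEB1 controls and at 4710, 925 and 2854 CPM in the ZEB1 knockouts.

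The higher epithelial genes in ZEB1 knockouts had a median log2 fold change of 0.47. Whether epithelial cells in the dissected muscle contributed stays open in part. The 4 detected markers outside the list, Krt10, Sfn, Perp and Trp63, had a median of -0.16 with an SE of 0.33 over markers. They stood at 1.23 to 10.1 CPM (without TMM scaling) in ZEB1 controls too, so they need not follow a few epithelial cells. Krt5, Krt14, Krt1 and Krt15 were at 0 CPM in both ZEB1 groups, which argues against cells that express these keratins as a source. Epithelial cells without them stay open. Epcam was at 0 CPM in ZEB1 controls and 0.022 CPM in ZEB1 knockouts, and Krt19 was lower (-1.20) while Krt18 was higher (2.15). Noise near the detection floor stays open, since the 5 members with a mean of at least 1 CPM in the ZEB2 line had a median of 0.60 with an SE of 0.48. The median was also 0.47 with the number of males as a covariate, which argues against sex as the whole source, but it was 0.14 without ZEB1_control 2, which left 1 control. Release of epithelial genes from ZEB1 repression may account for Spint2, Crb3, Marveld2, Llgl2 and Krt18, but this was not tested. Krt18 was also higher in ZEB2 knockouts (1.98 with an SE of 0.58, edgeR adjusted p = 0.0824). The size of the list effect stays open with 2 control libraries.

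Pseudogenes made up 9 of the 16 genes with an unadjusted p under 0.001 between the control groups, against 3.92% of genes tested (Fisher exact p = 1.83e-09, over genes that are not independent). Whether reads shared between near-identical copies lie behind this stays open. The 3 called pseudogenes shared a median of 70.0% of their 31-base words with their closest tested gene, but the 590 other tested pseudogenes that were searched shared a median of 75.1%, so this does not set the called ones apart. The sum of Rps3a1, Rps3a2 and Rps3a3 in ZEB2 over ZEB1 controls was -0.049 in log2 and does not separate moved reads from extra transcripts. Rps3a2 stood at 58.3, 74.4, 48.7 and 68.3 CPM in ZEB1_control 2 and the 3 ZEB1 knockouts and at 2.27 CPM in ZEB1_control 3, near the 1.88 to 3.08 CPM of the ZEB2 line, so this library resembled the ZEB2 line there, and a wrong label for it would change every ZEB1 value. At the 3 called pseudogenes both ZEB1 controls lay together and far from the ZEB2 line, with Gm3375 at 13.3 ± 2.99 CPM (SD, n = 2) against 0.220 ± 0.0506 (n = 3). A wrong label and a sequence variant within or between the mouse lines were not tested and stay open.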
